A study of Mus musculus with 4 samples.

How the data were processed

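Gene expression was measured by bulk RNA sequencing in 4 cell populations sorted from EO771 tumours, which grow from a mouse mammary carcinoma cell line. The populations were the CD103+ conventional dendritic cells of type 1 (cDC1), the CD11b+ conventional dendritic cells of type 2 (cDC2), a dendritic cell population with intermediate CD103 and with CD11b (called CD103int DC here) and macrophages. Each population had 1 library. Per the labels' protocols, RNA was extracted with a column kit and treated with DNase I, and libraries were made from total RNA with a directional kit. The labels do not state the gates of the sort, the number of mice or cells per library, or whether the tumours came from mice given the heterodimeric interleukin-15 named in the study's title.

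The values are an expression signal that the authors deposited in 1 table of 13976 genes, per the name of the deposited table CPM (counts per 1000000 reads) on library sizes scaled by the trimmed mean of M values, after a filter on genes. The values were never negative and were not on a log scale. The columns summed to 905670 (cDC1), 968810 (cDC2), 974649 (CD103int DC) and 1169350 (macrophage), so that the macrophage column exceeded 1000000, which plain CPM cannot do. The aligner, the counting program, the strand setting of the counting and the genome build are not given in the sources used here. All 13976 pairs of gene identifier and symbol in the table matched release M21 of the GENCODE mouse annotation (assembly GRCm38), and coordinates are given from that annotation. The rule of the authors' filter is not stated. The lowest maximum of any gene over the 4 libraries was 0.496 CPM. A symbol was shared by several entries for 34 of the 13976 entries, and these were kept apart by identifier.

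Depth was estimated from the values. In each column every value was a multiple of 1/100 of a step, and between 69.2% (cDC2) and 78.9% (cDC1) of the values above 0 were whole multiples of that step, at a tolerance of 0.001 of the step. The step was taken as the value of 1 read. It was 0.0204 CPM in the cDC1, 0.0216 CPM in the cDC2, 0.0174 CPM in the CD103int DC and 0.0183 CPM in the macrophage library. The column totals then stood for 44425900, 44940500, 55960000 and 63817500 estimated reads, to 6 digits, in the same order. Because the values were estimated counts and not whole reads, and because each group had 1 library, no count test was run. A value of 10 CPM stood for 491, 464, 574 and 546 estimated reads, with a counting error of 4.52%, 4.64%, 4.17% and 4.28%. Intervals printed with a level or fold are 95% Poisson or binomial intervals on these estimated reads. They cover counting error only, not the variation between animals, sorts or libraries, and amplified reads without molecular identifiers are not independent molecules. Where a gene is listed at 0 in a library, no fold is given, since a 0 can come from read assignment or from few molecules as well as from a low level.

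Libraries were grouped by the population in the labels, to which the column names were matched. Of the plans for several libraries and for 1 library per population, the second applied. With 1 library per population no test between populations was possible, and no p-value or standard deviation is given. Genes were compared by a rule of size. The difference between 2 libraries was taken on log2(CPM + 1), which understates the change of genes with low values. A gene was counted when this difference was at least 2 (4-fold) and the higher library had at least 10 CPM. All 6 pairs of libraries were compared in this way. Genes set apart in 1 library were those at least 2-fold above, or below, every other library on the same scale, with at least 10 CPM in the highest library. Folds printed for single genes are ratios of CPM, without the added 1. Similarity was measured by Pearson's r and Spearman's rho of log2(CPM + 1) across the 8724 genes with at least 10 CPM in any library. These correlations run across genes, which are not independent replicates.

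Gene lists for cell types and pathways were written from general knowledge before the data were examined, as were the comparisons, the thresholds and the alternatives tried, except for those named below as added. For each list the median difference over members with at least 1 CPM in either library was computed, with the number of members at least 2-fold higher or lower. The percentile printed beside a median is its place among the medians of 10000 random lists of the same size, matched on mean expression in 10 bins. It describes these libraries and is no test of the populations. It is given for lists with at least 3 measured members, and a list is called apart from other genes when it lies below 2.5 or above 97.5. Genes share lists (Maf and Irf8 stand in more than 1 list, for example), so lists are not independent of each other.

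The genes named in the text were chosen by a rule set before the data were examined. The rule takes the 10 genes with the largest difference each way in each comparison of the CD103int DC, the 10 farthest above and the 10 farthest below all others in that library, and the 5 largest each way in the other comparisons. Predicted gene models, mitochondrial genes and receptor segments were left out. It adds the sort genes Itgae and Itgam and up to 6 members of each list. How those 6 were split, as the 3 of highest mean CPM and the 3 of widest range, was settled after the data were seen. A gene outside the rule is named as such, and some genes that the rule names are not reported here.

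The computations used Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and figures were drawn with Matplotlib 3.10.9. The comparison was tested on simulated data of 13976 genes with 200 genes changed, drawn with counting error only. Variation between animals, sorts or libraries was not simulated, so the rates below are not those of false calls between real libraries. For the CD103int DC against cDC1 it recovered 98.8% of genes changed 6-fold and 100% of those changed 8-fold, and called 0 of those changed 3-fold and 0 unchanged genes. The list percentile, on 60 simulated lists in that comparison, left 91.7% of unshifted lists inside the range of 2.5 to 97.5 and placed 100% of lists shifted 2-fold above it. The alternatives tried were other added constants (0.25 and 5), other minimum levels, other sizes of difference, each column rescaled to a total of 1000000, scaling by the median ratio to the geometric mean, and the mean in place of the median of a list. Added after the data were seen were a table without ribosomal, mitochondrial and small RNA entries, and counts without the macrophage or the cDC1 library.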

Results

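RNA from 4 myeloid populations of EO771 tumours was sequenced, with 1 library each for cDC1, cDC2, CD103int DC and macrophages. The study's title links an interleukin-15 treatment given near the tumour to the accumulation of the CD103int DC, and the design asks how this population compares with the conventional dendritic cells (DC) and the macrophages of the same tumour type. The table held 13976 genes, of which 11685 were protein coding. The depth came to about 44425900 (cDC1), 44940500 (cDC2), 55960000 (CD103int DC) and 63817500 (macrophage) estimated reads. Between 7732 and 7909 genes had at least 10 CPM in a library. All levels are in CPM as scaled by the authors, and where 4 values follow each other they are in the order cDC1, cDC2, CD103int DC and macrophage. A range after a level or fold is its 95% interval from counting error. No population had a replicate library, so no difference here was checked against replicate error.

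The RNA content of the libraries differed outside the protein-coding genes. Gm26917 and Gm42418, gene models in which ribosomal RNA reads collect and which were singled out after their values were seen, held 12.5%, 5.94%, 7.08% and 11.3% of the column totals, and protein-coding genes held 77.0%, 80.7%, 80.9% and 76.9%. The cDC1 library listed 454 genes at 0, the others 19, 10 and 20. Rescaling all columns to equal totals moved the median log2 difference over genes of the CD103int DC against macrophage by 0.26, against cDC1 by -0.11 and against cDC2 by -0.01. The same rescaling moved cDC1 against cDC2 by 0.10, cDC1 against macrophage by 0.37 and cDC2 against macrophage by 0.27. The macrophage column carried another name prefix than the 3 DC columns, and what it stands for is not stated. If it marks a batch, that batch and the macrophage group cannot be told apart in any comparison with the macrophage library.

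The genes of the sort markers followed the labels. Itgae (CD103; ENSMUSG00000005947.11, chromosome 11, 73090583 to 73147446, plus strand) stood at 77.0 (74.5 to 79.5) CPM in cDC1, 1.1 (0.819 to 1.45) in cDC2, 13.2 (12.3 to 14.2) in CD103int DC and 5.50 (4.89 to 6.16) in macrophages. Its level in the CD103int DC was thus 5.83-fold (5.39 to 6.31) below that of cDC1 and 12-fold (9.04 to 16.3) above that of cDC2. Itgam (CD11b; ENSMUSG00000030786.18, chromosome 7, 128062640 to 128118491, plus strand) was low in cDC1, at 36.7 (35.0 to 38.4) CPM, and stood at 638 (631 to 646), 688 (681 to 695) and 945 (937 to 953) CPM in the other libraries. Itgae shares its locus with Haspin on the opposite strand and Itgam with Gm49368 on the same strand.

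Lineage markers fixed beforehand set the cDC1 library apart from the other 3. The cDC1 chemokine receptor gene Xcr1 was at 130.5, 1.72, 9.13 and 8.28 CPM, Gcsam at 38, 0.0431, 2.65 and 1.85, Cd8a at 50.2, 4.53, 1.18 and 4.16, and the cross-presentation factor Wdfy4 at 1728, 297, 449 and 511. Among genes common to conventional DC, the growth factor receptor Flt3 (179, 15.8, 21 and 32.6 CPM), the transcription factor Zbtb46 (152, 22.0, 47.5 and 20.9), Bcl11a (354, 26.9, 28.4 and 32.8) and Spib (48.6, 6.94, 4.18 and 7.40) were also highest in cDC1. The integrin gene Itgax (CD11c) was not, at 769.7, 1438, 1280 and 516 CPM. Of the 9 measured pan-cDC markers, 8 were at least 2-fold higher in cDC1 than in cDC2 (median 2.64, percentile 100) and 8 at least 2-fold higher than in macrophages (median 2.56, percentile 100). Plasmacytoid DC markers moved with them, by 2.90 and 3.19 in the same comparisons, and Flt3, Bcl11a and Spib are also expressed by plasmacytoid DC. Macrophage genes ran the other way. The growth factor receptor Csf1r was at 409, 1096, 925 and 1538 CPM, the transcription factor Maf at 8.79, 148, 85.7 and 231, and the lysosomal Gpnmb at 4.89, 129, 54.5 and 190.3. The library labelled cDC2 carried macrophage markers at about the level of the macrophage library, where 4 of 18 members were at least 2-fold higher and 1 at least 2-fold lower in cDC2 (median -0.02, percentile 78.2, or 0.25 with columns rescaled to equal totals, 0.07 with median-ratio scaling and a mean of 0.31). The DC lists did not separate these 2 libraries. cDC2 markers had 1 higher and 2 lower of 14 (median 0.04, percentile 87.9, mean -0.02). Pan-cDC markers had 1 higher and 1 lower of 9 (median -0.23, percentile 20.5, or 0.02 with columns rescaled to equal totals).

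**Figure D1:**
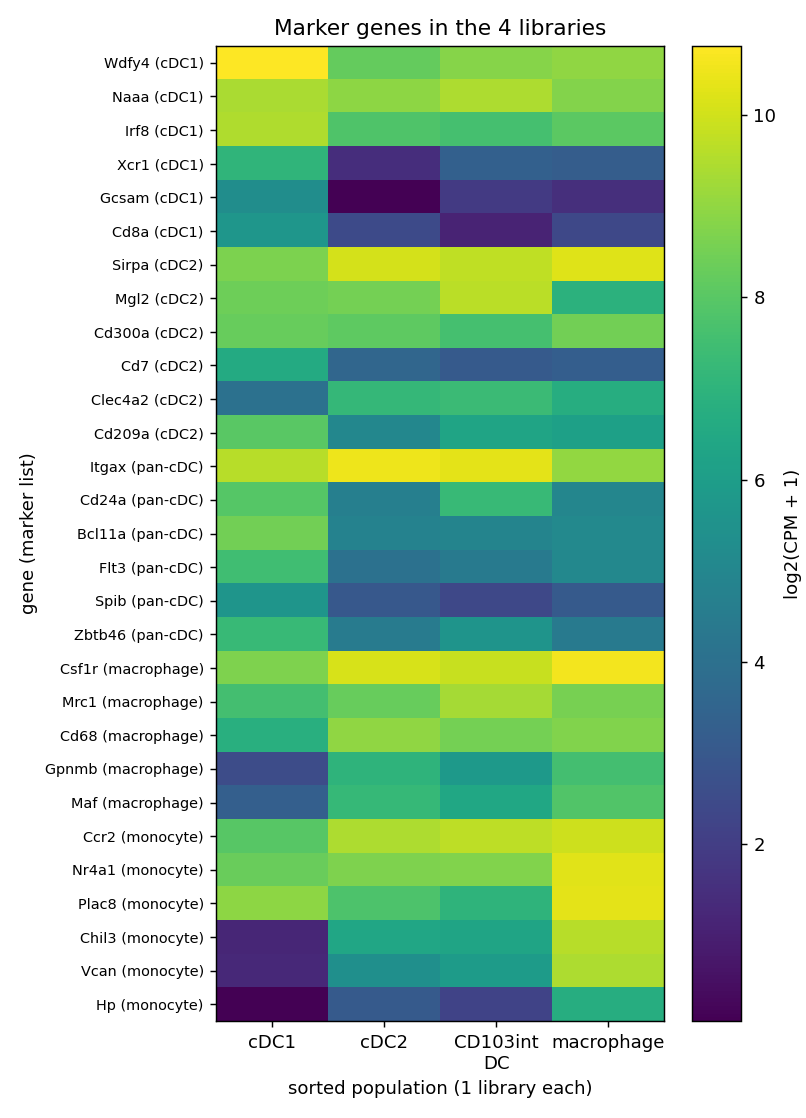
Marker genes of 5 lists (y axis, list in parentheses) in the 4 libraries (x axis, 1 library each), with the colour giving log2(CPM + 1). The cDC1 column is bright for Wdfy4, Irf8 and Flt3 and dark for Maf, Vcan and Hp, while the other 3 columns resemble each other outside the monocyte genes.

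Across the 8724 genes with at least 10 CPM in any library, the CD103int DC profile was nearest to cDC2 (r = 0.977, rho = 0.976), then to macrophages (r = 0.918, rho = 0.918), then to cDC1 (r = 0.863, rho = 0.870). The cDC2 profile lay nearer to macrophages (r = 0.946, rho = 0.947) than to cDC1 (r = 0.834, rho = 0.845), and cDC1 was farthest from macrophages (r = 0.792, rho = 0.806). The 4-fold counts kept this order among the pairs of the CD103int DC, with 17 genes against cDC2, 177 against macrophages and 390 against cDC1.

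**Figure D2:**
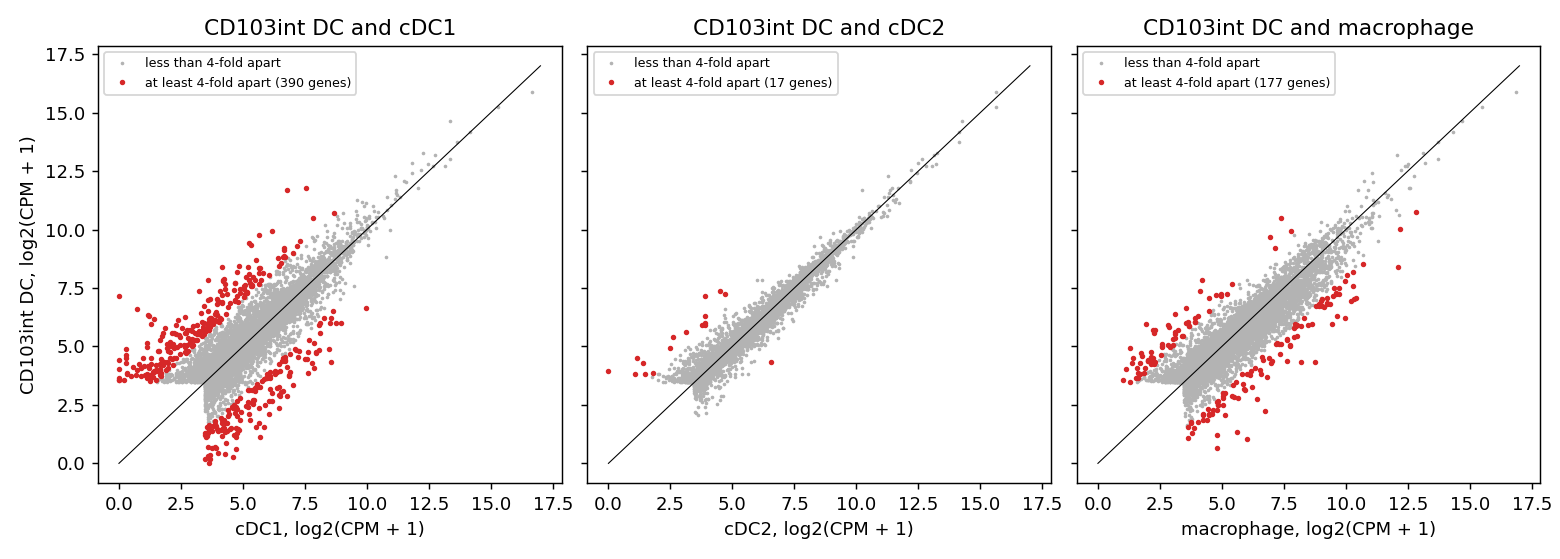
Each point is a gene with at least 10 CPM in the higher of the 2 libraries, with the CD103int DC on the y axis and cDC1, cDC2 or macrophage on the x axis, both as log2(CPM + 1), and the line marks equal levels. Red points are at least 4-fold apart and number 390 against cDC1, 17 against cDC2 and 177 against macrophage.

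Set against cDC2, its nearest library, the CD103int DC library had more transcripts of a small group of receptors and enzymes. Il1rl1, the receptor for interleukin-33, Aldh1a2, an enzyme that makes retinoic acid, and Retnla, a secreted resistin-like protein of alternatively activated macrophages, stood at the top of them. Genes of DNA replication such as Top2a and Rrm2 were also higher, while interferon response genes, complement genes and the peptidase gene Ace were lower. MHC class II genes such as Cd74 were level. Of 8119 genes, 16 were at least 4-fold higher and 1 at least 4-fold lower (16 and 4 with columns rescaled to equal totals, 25 and 15 with a minimum of 1 CPM in place of 10), and 127 and 54 differed at least 2-fold. Il1rl1 was 17.8-fold (13.7 to 23.7) higher, Retnla 10.2-fold (9.39 to 11.0) and Aldh1a2 11.6-fold (9.16 to 14.8). Fcrls (7.6-fold), Cd226 (6.11-fold), Cd24a (6.07-fold), the lectin receptor gene Asgr2 (6.41-fold) and the co-receptor gene Gfra2 (5.56-fold) were also higher. Hist1h4m was listed at 0 in cDC2 and at 14.6 CPM in the CD103int DC, but it is 1 of 11 near-identical histone genes whose sum was 324 and 630 CPM. The 1 gene at least 4-fold lower was Ace, angiotensin-converting enzyme (lower by 4.91-fold, 4.59 to 5.25). The next lowest by the rule, which differed by less than 4-fold on log2(CPM + 1), were the collagen genes Col1a1 (20.1 CPM in cDC2, 4.81 in CD103int DC) and Col3a1 (14.3 and 3.45), Cd300e (48.2 and 13.1), the chemokine gene Ccl8 (21.3 and 5.54), Cd4 (23.3 and 6.36), Gpr31b (22.4 and 6.38), the fractalkine receptor Cx3cr1 (40.4 and 13), Fpr1 (11.3 and 3.15) and Adgre4 (57.2 and 19.7).

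Proliferation genes had the highest median of the lists of cell types and pathways in the CD103int DC against cDC2, with 10 of 17 members at least 2-fold higher and 0 lower (median 1.13, percentile 100). Top2a, an enzyme that untangles replicated DNA, was at 86.3 against 34.6 CPM, Rrm2, which makes deoxynucleotides, at 23.4 against 9.57, and Stmn1 at 51.6 against 22.2. Pcna stood at 165 and 150.1 CPM. cDC1 markers had a median of 0.46 (percentile 100), with 3 of 15 at least 2-fold higher, among them Xcr1 (9.13 against 1.72 CPM) and Gcsam (2.65 against 0.0431), and Cd8a lower (1.18 against 4.53). cDC2 markers had a median of 0.26 (percentile 99.9), with Mgl2 at 807 against 368 CPM and Cd209a at 78.8 against 31.5, and pan-cDC markers one of 0.13 (percentile 92.7). Macrophage markers were lower in the CD103int DC (5 of 18 at least 2-fold lower and 2 higher, median -0.75, percentile 0), with Gpnmb at 54.5 against 129 CPM and the mannose receptor Mrc1 the other way, at 633 against 311. Monocyte markers had a median of -0.55 (percentile 0) and complement genes one of -0.77 (percentile 0), with C3 at 349 against 565 CPM and C3ar1 at 152 against 303.

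Interferon response genes were lower in the CD103int DC than in cDC2 by less than 2-fold each. The type I list had 17 of 17 members within 2-fold (median -0.52, percentile 0) and the interferon gamma list 14 of 14 (median -0.47, percentile 0). Examples were Irf7 (366 against 636 CPM) and Gbp5 (73.6 against 107). MHC class II genes were level (median 0.02, percentile 48.4), with Cd74 at 9384 and 9057 CPM. MHC class I genes (median -0.25, percentile 0.05), pattern receptors (median -0.44, percentile 0), lysosomal enzymes (median -0.25, percentile 0) and lipid handling genes (median -0.23, percentile 0.210) had medians a little below 0. So did chemokine ligands (median -0.33, percentile 0.02), chemokine receptors (median -0.25, percentile 1.34), cytokines (median -0.24, percentile 0.410) and costimulatory and coinhibitory ligands (median -0.18, percentile 0.590). Transcription factors (median -0.12, percentile 0.670) and phagocytosis receptors (median -0.14, percentile 2.18) differed less, glycolysis genes were slightly higher (median 0.17, percentile 99.6), and matrix and wound genes were level (median -0.03, percentile 27.7, mean 0.19). For mature or migratory DC genes the median was -0.08 (percentile 11.3), and for the interleukin-15 and interleukin-2 pathway -0.09 (percentile 10.7). In that pathway Il2rb, the shared beta chain of both receptors, stood at 0.644 against 8.13 CPM, moving with the NK and T cell genes Prf1 (0.0523 against 3.23), Nkg7 (0.139 against 1.98) and Lck (0.435 against 4.10). Il15 (6.25 and 6.70) and Il2rg (158 and 206) differed less.

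Markers of other cells were lower in the CD103int DC than in cDC2. T cell markers had 6 of 9 members at least 2-fold lower and 2 higher (median -1.18, percentile 0), with Cd3e at 0.0174 against 1.79 CPM, the 2 being Cd6 (13.1 against 5.28) and Cd2 (higher by 5.21-fold). NK cell markers had 4 of 6 lower (median -1.52, percentile 0), with Gzmb at 0.209 against 4.66 CPM, and fibroblast markers 5 of 6 lower (median -1.70, percentile 0). All of these levels in cDC2 were below 25 CPM, except for Klrk1, at 83.9 against 91.4 CPM. Langerhans cell markers were higher, with 2 of 4 at least 2-fold (median 0.98, percentile 100), including Epcam (4.28 against 1.23 CPM) and Gfra2.

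Against cDC1 the CD103int DC library was set apart by myeloid, tissue remodelling and inflammatory genes on one side and DC lineage genes on the other. The arginine-degrading enzyme gene Arg1, the matrix genes Fn1 and Vcan, the complement receptor gene C5ar1 and the macrophage transcription factor gene Maf were far higher. The cDC1 genes Xcr1, Irf8 and Cd8a and the DC genes Flt3 and Zbtb46 were lower. Of 8443 genes, 235 were at least 4-fold higher and 155 at least 4-fold lower (773 and 461 at least 2-fold). Leaving out ribosomal, mitochondrial and small RNA entries, a setting chosen after the data were seen, gave 213 each way. Retnla was listed at 0 in cDC1 and at 142 CPM in the CD103int DC. Arg1 was 143-fold (102 to 208) higher, Lyz1 64.3-fold (50.1 to 84), the chitinase-like Chil3 59.3-fold (46.4 to 76.9), fibronectin (Fn1) 30.6-fold (29.8 to 31.5), C5ar1 42.5-fold (34.1 to 53.7) and versican (Vcan) 42.5-fold (33.5 to 54.6). Fam20c, Anxa3 and Ear2 were higher by 140.1-fold, 106-fold and 20.6-fold. Lower were Cd8a, by 42.4-fold (33.3 to 54.7), and the gut-homing receptor Ccr9, by 28.9-fold (24.0 to 35.3), as were Mctp2 (49.2-fold), Ptprf (21.2-fold), Sla2 (23.3-fold), Gpr141b (19.9-fold), Chl1 (17.3-fold) and Adam11 (21.2-fold). Pagr1a (23.1, 5.93, 0.224 and 3.60 CPM) also met the rule, but it overlaps Gm42742 on the same strand, and their sum was 23.1, 19.1, 20.8 and 13.9 CPM.

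By lists, 11 of 15 cDC1 markers were at least 2-fold lower in the CD103int DC than in cDC1 and 0 higher (median -1.94, percentile 0), as were 6 of 9 pan-cDC markers (median -1.66, percentile 0). Plasmacytoid DC markers, Ccr9 among them, moved with them by a larger median (6 of 6 lower, median -3.09, percentile 0), and Irf8 and Cd8a are also expressed by plasmacytoid DC. Naaa did not follow, at 697 and 682 CPM. Of 18 macrophage markers, 16 were at least 2-fold higher and 1 lower (median 2.58, percentile 100), and of 14 monocyte markers 7 were higher and 2 lower (median 1.05, percentile 100). cDC2 markers were split, with 5 of 13 at least 2-fold higher and 4 lower (median 0.65, percentile 99.8): Sirpa was at 837 against 399.7 CPM and Clec4a2 at 163 against 15.6, but Cd209a at 78.8 against 257 and Cd7 at 7.52 against 97.1. Matrix and wound genes (14 of 17 higher, median 2.43, percentile 100) included Thbs1 (19.8-fold) and Mmp13 (9.52-fold). Chemokine ligand genes (13 of 15 higher, median 2.20, percentile 100) included Ccl6 (14.0-fold), Ccl9 (16.9-fold) and Cxcl2 (13.3-fold), and Ccl7 was listed at 0 in cDC1 and at 11.4 CPM in the CD103int DC. Complement genes (8 of 12 higher, median 2.66, percentile 100) included C3 (12.7-fold) and Cfb (12.9-fold). Lipid handling genes (13 of 14 higher, median 1.43, percentile 100) included Lpl (17.4-fold) and Trem2 (22.1-fold).

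Cytokine genes were higher in the CD103int DC than in cDC1 for 10 of 14 members (median 1.68, percentile 100), among them Il1b (3.17-fold), Il1rn (13.2-fold), Tnf (8.42-fold) and Il15 (5.11-fold, from 1.22 to 6.25 CPM). Pattern receptors (10 of 16 higher, median 1.37, percentile 100), lysosomal enzymes (12 of 18, median 1.37, percentile 100), phagocytosis receptors (8 of 14, median 1.28, percentile 100) and interferon gamma response genes (8 of 14, median 1.18, percentile 100) were higher too. Examples were Clec4n (4.68-fold), Lgmn (4.31-fold), Axl (4.71-fold) and Gbp4 (5.09-fold). Glycolysis genes had 6 of 16 members higher (median 0.83, percentile 100) and transcription factors 8 of 22 higher and 4 lower (median 0.59, percentile 100), with Cebpb 9.18-fold higher and Irf8 3.65-fold lower. Chemokine receptors had 4 higher and 4 lower of 10, so that the median was 0.77 (percentile 99.7) and the mean -0.24. MHC class I genes were slightly lower and apart from random lists (median -0.15, percentile 2.02). Inside the range of random lists were MHC class II (median -0.06, percentile 13.1), type I interferon response (median 0.06, percentile 40.6, or -0.04 with columns rescaled to equal totals) and proliferation genes (median -0.17, percentile 8.46). Costimulatory and coinhibitory ligands (median 0.26, percentile 88.3), mature or migratory DC genes (median -0.20, percentile 5.98) and the interleukin-15 and interleukin-2 pathway (median -0.16, percentile 12.9) had members on both sides. Il4i1, an amino acid oxidase of mature DC, was 9.58-fold lower, and Pdcd1lg2 (PD-L2) 3.45-fold higher.

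Against macrophages the CD103int DC library was lower in monocyte and interferon genes and higher in MHC class II and proliferation genes. The interferon-induced Rsad2 and Ifit2, the monocyte genes Plac8, Hp and Vcan and the matrix gene Thbs1 were lower. The chemokine gene Ccl17, which attracts T cells, the MHC gene H2-Ab1, the lectin gene Mgl2 and the replication gene Top2a were higher. Of 8254 genes, 69 were at least 4-fold higher and 108 at least 4-fold lower, and 359 and 686 differed at least 2-fold. This balance followed the scaling, with 113 higher and 67 lower when columns were rescaled to equal totals. With ribosomal, mitochondrial and small RNA entries left out, as chosen after the data were seen, 117 were higher and 81 lower. The genes farthest above were Ccl17, a chemokine made by DC (21.7-fold, 18.4 to 25.6), Asgr2 (20.6-fold, 16.4 to 26.2), Hr (13-fold), Ccdc80 (13.9-fold), the lipoxygenase Alox15 (12.9-fold), Ephx1 (12.4-fold), the fusion protein gene Dcstamp (11.0-fold), Fcrls (10.1-fold), Slc27a3 (9.98-fold) and macrophage elastase (Mmp12, 8.6-fold). Among the genes farthest below were Cd177 (59.9-fold, 46.6 to 78.5), haptoglobin (Hp, 28.8-fold, 25.1 to 33.2), Ace (22.6-fold), Slpi (31.7-fold), Slfn4 (13.6-fold), thrombospondin 1 (Thbs1, 13.2-fold, 13.1 to 13.4), Arhgef37 (14.9-fold), Serpinb10 (20.7-fold) and Vcan (11.3-fold).

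All 17 type I interferon response genes were at least 2-fold lower in the CD103int DC than in the macrophage library (median -2.14, percentile 0), with Rsad2 at 123 against 1184 CPM, Ifit2 at 189 against 1233 and Irf7 at 366 against 1648. Monocyte markers were lower for 12 of 14 members (median -2.51, percentile 0), with Chil3 at 78.5 against 788 CPM and Plac8 at 128 against 1276, and Ccr2 at 832 and 978. Neutrophil markers moved the same way, with 2 of 4 lower (median -1.07, percentile 0.170). Interferon gamma response genes were lower for 11 of 14 (median -1.22, percentile 0), with Cxcl10 at 112 against 605 CPM. Lists with lower medians also included pattern receptors (median -0.98, percentile 0), complement (median -0.88, percentile 0.0800), costimulatory and coinhibitory ligands (median -0.80, percentile 0.0100), cytokines (median -0.70, percentile 0.0100), transcription factors (median -0.68, percentile 0.0700), chemokine receptors (median -0.59, percentile 0.990) and the interleukin-15 and interleukin-2 pathway (median -0.64, percentile 0.400). Il15 was at 6.25 against 23.7 CPM, Il15ra at 5.70 against 24.6, PD-L1 (Cd274) at 138 against 419.8, Il1b at 735 against 2495 and Tlr7 at 37.4 against 197.

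Higher than in macrophages were 15 of 17 proliferation genes (median 1.71, percentile 100), with Top2a at 86.3 against 22.9 CPM and Stmn1 at 51.6 against 8.47. MHC class II genes had 4 of 12 at least 2-fold higher and 0 lower (median 0.97, percentile 100), with H2-Ab1 at 5454 against 2147 CPM, Cd74 at 9384 against 4334 and H2-DMb2 at 200.3 against 41.3. Glycolysis genes were higher by less (median 0.47, percentile 100). Macrophage markers were mixed, with 4 of 18 higher and 5 lower (median -0.28, percentile 16.6). The medians of cDC1 markers (median 0.13, percentile 81.9), cDC2 markers (median 0.19, percentile 95.9) and pan-cDC markers (median 0.19, percentile 89.4) were a little above 0, and Mgl2 stood out at 807 against 120.4 CPM. Chemokine ligands (median 0.06, percentile 63.8, mean -0.16), matrix and wound genes (median 0.10, percentile 88.3) and MHC class I genes (median -0.46, percentile 8.59) lay inside the range of random lists. So did phagocytosis receptors (median -0.10, percentile 38), lysosomal enzymes (median -0.12, percentile 64.2) and lipid handling genes (median -0.15, percentile 35.4), whose medians became 0.08, 0.14 and 0.11 with columns rescaled to equal totals. For mature or migratory DC genes the median was -0.41 (percentile 1.49) but the mean 0.15, with Ccl17 higher and Birc3 at 90.1 against 184 CPM.

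**Figure D3:**
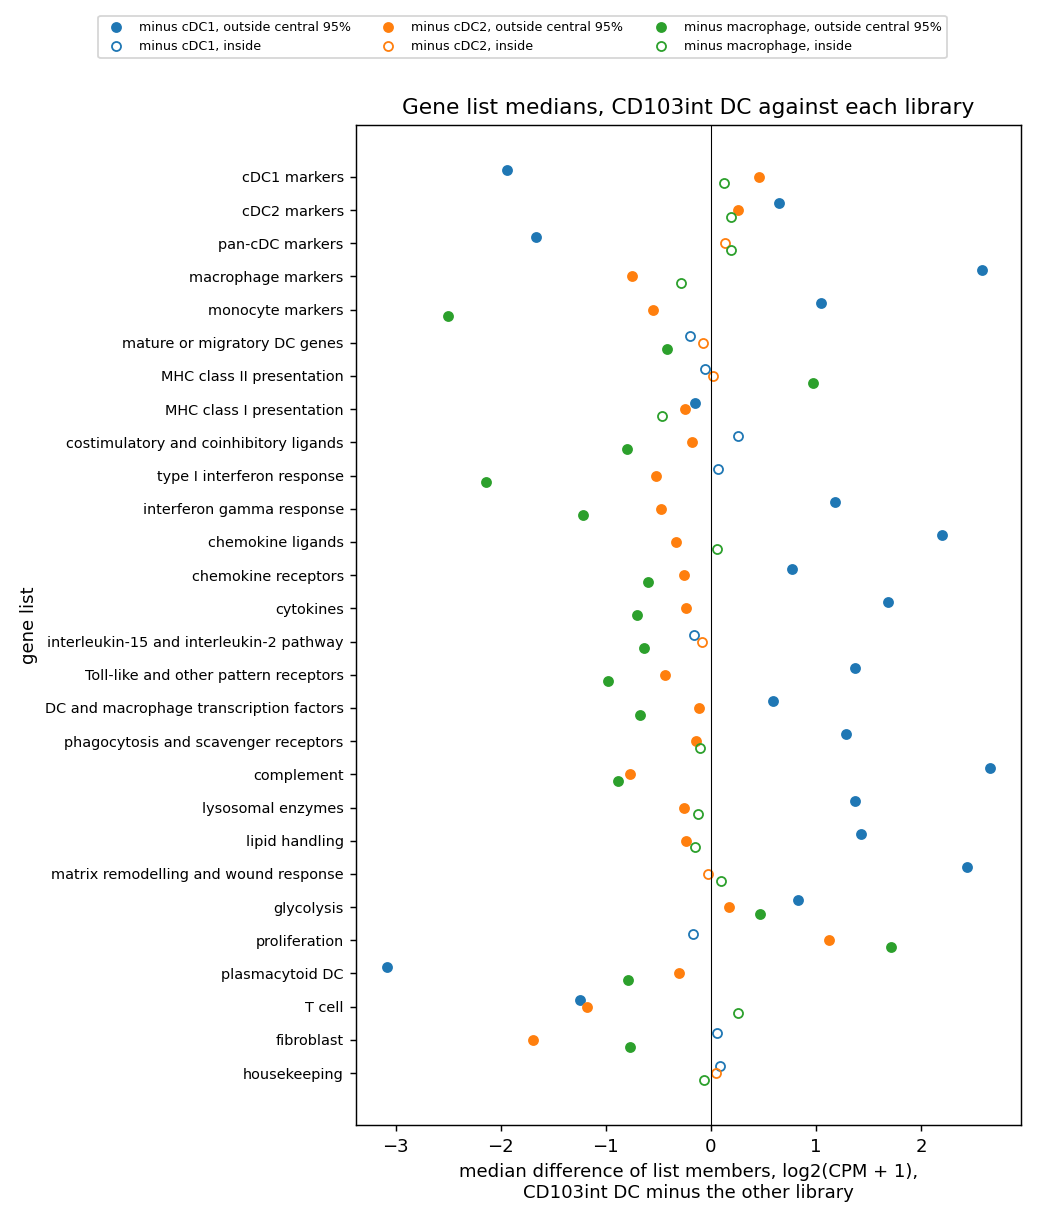
Median difference in log2(CPM + 1) over the members of each gene list (x axis) for the CD103int DC minus cDC1 (blue), cDC2 (orange) and macrophage (green), 1 library each, with lists of at least 5 members measured in each comparison on the y axis. Filled points lie outside the central 95% of random lists. The largest medians are -3.09 for plasmacytoid DC genes and 2.66 for complement genes, both against cDC1.

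The CD103int DC library had 28 genes at least 2-fold above every other library and 6 at least 2-fold below. The same counts were 334 and 612 for cDC1, 11 and 15 for cDC2, and 334 and 58 for macrophages. Without the cDC1 library, a setting chosen after the data were seen, 101 genes were highest in the CD103int DC by this rule. The 10 farthest above led with Aldh1a2 (ENSMUSG00000013584.5, chromosome 9, 71215789 to 71296243, plus strand), at 0.204, 1.62, 18.7 and 1.61 CPM, and Fcrls (ENSMUSG00000015852.13, chromosome 3, 87250758 to 87263738, minus strand), at 8.50, 21.8, 165 and 16.4 CPM. Asgr2 (ENSMUSG00000040963.15, chromosome 11, 70092644 to 70106187, plus strand) was at 3.61, 4.59, 29.5 and 1.43 CPM, Il1rl1 (ENSMUSG00000026069.15, chromosome 1, 40429570 to 40465415, plus strand) at 0.224, 1.23, 21.9 and 3.72 and Retnla (ENSMUSG00000061100.4, chromosome 16, 48842551 to 48844461, plus strand) at 0, 14.0, 142 and 29.9. The fatty acid transporter Slc27a3 (11.0, 12.7, 60.2 and 6.03), the ribonuclease Ear2 (11.1, 62.0, 228 and 63.0), the actin-binding Palld (5.40, 8.28, 30.3 and 4.97), the lysozyme gene Lyz1 (1.26, 24.0, 81.3 and 22.4) and Hr (52.0, 71.9, 228 and 17.6) completed the 10. Of the other 18, Fn1 was the most abundant, at 109, 1195, 3325 and 1422 CPM, followed by Mgl2, a lectin of cDC2 and of alternatively activated macrophages, at 337, 368, 807 and 120.4. They also included Alox15 (6.28, 16, 51.6 and 3.99) and, chosen after its values were seen, the proliferation marker Mki67 (42.7, 25.1, 95.8 and 32.3). The farthest below were Pagr1a, with the overlap given above, Cx3cr1 (61.3, 40.4, 13 and 94.5 CPM), Cd8a, Il2rb (11.0, 8.13, 0.644 and 2.66, with NK and T cell genes), Gria3 (18.8, 2.78, 0.836 and 4.16) and Setbp1 (11.9, 1.62, 0.279 and 1.61). Below by less than 2-fold on log2(CPM + 1) were Ets1 (13.7, 11.9, 5.47 and 21.2), Ablim1 (12.4, 3.06, 0.575 and 2.13), P2ry13 (24.4, 22.2, 10.8 and 35.7) and Enpp4 (10.9, 14.0, 5.54 and 11.3).

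**Figure D4:**
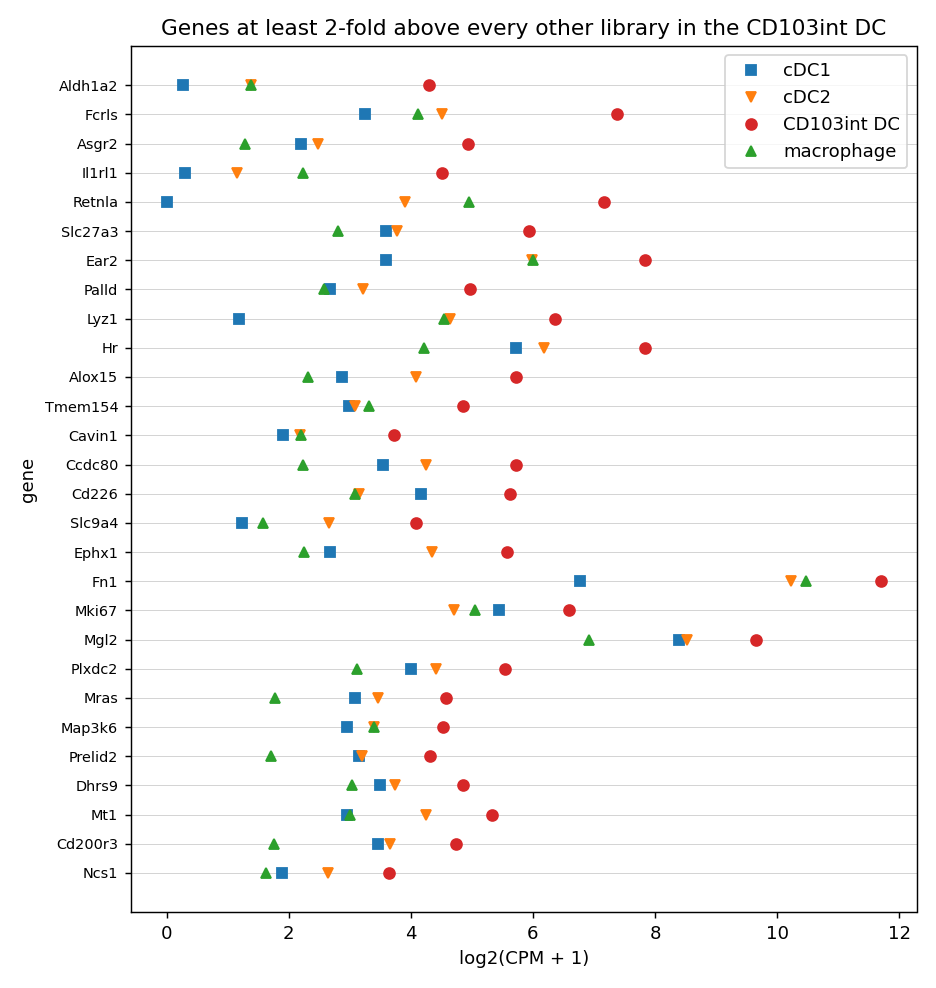
Levels (x axis, log2(CPM + 1)) of the 28 genes (y axis) at least 2-fold above every other library in the CD103int DC, 1 point per library. The red points lie to the right of all others, by between 1.01 and 2.91 on this scale.

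The libraries labelled cDC1 and cDC2 differed by lineage genes, with the chemokine receptor gene Xcr1 higher in cDC1 and macrophage, chemokine and complement genes such as C5ar1 higher in cDC2. cDC1 differed from cDC2 in 198 genes at least 4-fold higher and 304 at least 4-fold lower of 8459 (228 and 276 with columns rescaled to equal totals, 269 and 284 without ribosomal, mitochondrial and small RNA entries). Highest in cDC1 were Gpr141b (233-fold, 136 to 438), Xcr1 (75.6-fold, 60.7 to 95.5), Gcsam (881-fold, 244 to 7279), Itgae (70.0-fold) and the phosphatase gene Ptprf (50.3-fold). The Gcsam fold rests on 0.0431 CPM in cDC2, fewer than 3 estimated reads. Lowest were C5ar1 (76.6-fold, 61.5 to 96.6), Chil3 (63.0-fold, 49.3 to 81.8), Arg1 (88.8-fold), the itaconate-making enzyme gene Acod1 (59.2-fold) and cathepsin K (Ctsk), listed at 0 in cDC1 and at 28.7 CPM in cDC2. Proliferation genes were higher in cDC1 (12 of 17, median 1.20, percentile 100) along with cDC1 markers (10 of 15, median 2.41, percentile 100). Macrophage markers (16 of 18 lower, median -3.60, percentile 0), complement (9 of 12, median -3.80, percentile 0), chemokine ligands (14 of 14, median -2.86, percentile 0) and lipid handling genes (14 of 14, median -1.93, percentile 0) were lower. The cDC2 marker list did not separate them (5 higher and 4 lower of 14, median -0.22, percentile 15.6, mean 0.20), nor did MHC class II genes (median 0.03, percentile 76.0).

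Macrophages had more transcripts of monocyte genes such as Vcan, Plac8 and Hp than cDC1 and cDC2, and more of the neutrophil surface gene Cd177. Against macrophages, cDC1 had 218 genes at least 4-fold higher and 472 lower of 8468 (341 and 316 with columns rescaled to equal totals, 388 and 340 without ribosomal, mitochondrial and small RNA entries). The largest differences were Chl1 (29.2-fold), Wfikkn2 (29.8-fold), the lipoxygenase Alox5 (21.6-fold), Ngfr (20.3-fold) and Prima1 (63.3-fold) on the cDC1 side. On the macrophage side stood Chil3 (595-fold), Vcan (480.3-fold), Thbs1 (262-fold), Slfn4 (80.6-fold) and Hp (1724-fold, 589.7 to 8363). The Hp fold rests on 0.0612 CPM in cDC1, which stood for 3 estimated reads. The cDC2 library had 20 genes at least 4-fold higher than macrophages and 46 lower of 8141 (38 and 27 with columns rescaled to equal totals, 32 and 31 without those entries). Ccl17 (12.1-fold), H2-M2 (10.5-fold), Mmp12 (7.42-fold), Dcstamp (7.28-fold) and Ksr2 (9.81-fold) led on the cDC2 side. Cd177 (86.9-fold), Thbs1 (17.1-fold), Vcan (16.6-fold), coagulation factor F5 (52.3-fold) and Hist1h4m, listed at 0 in cDC2 and at 11.6 CPM in macrophages, led on the other. MHC class II genes were higher in cDC2 than in macrophages (5 of 12 at least 2-fold, median 0.88, percentile 100), while 12 of 17 type I interferon response genes (median -1.57, percentile 0) and 12 of 14 monocyte markers (median -2.26, percentile 0) were at least 2-fold lower. In the same 2 lists cDC1 had 14 (median -2.23, percentile 0) and 12 (median -2.57, percentile 0) members lower than macrophages. Neutrophil markers moved the same way, with 3 of 4 lower in cDC2 (median -1.23, percentile 0.0100) and 3 of 4 lower in cDC1 (median -1.93, percentile 0.120). Matrix and wound genes were lower in cDC1 than in macrophages (14 of 17, median -2.58, percentile 0), but did not separate cDC2 from macrophages (3 higher and 3 lower of 17, median -0.16, percentile 36.2, or 0.11 with columns rescaled to equal totals).

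Housekeeping genes in the CD103int DC had medians of 0.09 against cDC1 (-0.02 with columns rescaled to equal totals), 0.05 against cDC2 (mean -0.01) and -0.06 against macrophages (0.18 with columns rescaled to equal totals, 0.01 with median-ratio scaling). Actb was at 18310, 17858, 18538 and 20750 CPM. Among the named genes, those that overlap another annotated gene on the same strand were Anxa3, C3, Ccr9, Cd3e, Cd74, Cfb, Chl1, Clec4a2, Col3a1, Csf1r, Cx3cr1, Ephx1, F5, Gbp4, Gria3, Il2rg, Il4i1, Irf8, Itgam, Ksr2, Lck, Mctp2, Mrc1, Pagr1a, Palld, Ptprf, Runx2, Serpinb10, Slpi, Stmn1, Tcf4, Top2a and Zbtb46. Those that overlap one on the opposite strand were Ablim1, Ace, Adgre4, Aldh1a2, Bcl11a, Ccl6, Ccr9, Cd274, Cd3e, Cd7, Cebpb, Chl1, Csf1r, Cx3cr1, Cxcl10, Ear2, Ets1, F5, Flt3, Fn1, Il1b, Il4i1, Irf7, Itgae, Krt8, Maf, Mctp2, Mki67, Mmp12, P2ry13, Palld, Pdcd1lg2, Runx2, Sla2, Thbs1, Top2a, Vcan and Wdfy4. How the authors' counting divided reads between overlapping genes, and whether it used the strand, is not stated. Members of gene families of near-identical sequence, such as Lyz1, Ear2, Hist1h4m, Gbp4 and the H2 genes, are uncertain for the same reason.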

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

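Of the settings named here, the table without ribosomal, mitochondrial and small RNA entries and the counts without the macrophage or the cDC1 library were chosen only after the results were seen. No paired analysis was possible because each population had 1 library and the labels carry no replicate numbers. For the same reason leaving out replicates, a replicate block and a count test on recovered reads, planned for the case of several libraries, were not run. Gene counts stayed within 1.5 times the reported ones in 34 of 60 alternatives. The share of genes higher or lower moved with the scaling in the comparisons with macrophages and in the other pairs for which both splits are printed in the results, and genes of low level shift less than others on this scale. The order of the CD103int DC correlations (cDC2, then macrophage, then cDC1) held in all 5 alternatives tried for them. List medians stayed inside their interval in 994 of 1023 alternatives over 173 medians, and lists with fewer than 5 measured members were not recomputed. Of 7956 alternative values for the genes the rule names, 5818 stayed inside the counting interval, 2138 moved and 0 of those at least 2-fold apart changed sign. The last count was fixed in advance. Only the added constant and median-ratio scaling were varied here. A constant cannot reverse a sign, and that scaling shifted a pair by at most 0.12 on the log2 scale. Counting depth limits genes of low level most. The counting error takes reads as molecules, which may not hold for the cDC1 library, where the test of distinct molecules gave a ratio of 1.84. No setting replaces the missing replicates.

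In the order CD103int DC against cDC1, cDC2 and macrophage, then cDC1 against cDC2 and macrophage, then cDC2 against macrophage, the reported counts at 4-fold were 390, 17, 177, 502, 690 and 66. With 5 added to the CPM they were 216, 8, 98, 290, 428 and 41. With a minimum of 50 CPM they were 193, 8, 102, 266, 401 and 42, since fewer genes enter. An 8-fold size gave 129, 3, 30, 178, 251 and 17, and a 2-fold size 1234, 181, 1045, 1424, 2119 and 634. A minimum of 1 CPM and no minimum each gave 40 genes for CD103int DC against cDC2, of which 25 were higher and 15 lower. Genes highest in the CD103int DC, 28 as reported, numbered 54 with a minimum of 1 CPM, 54 with no minimum, 11 with a minimum of 50 CPM, 6 at 4-fold and 101 without the cDC1 library. They numbered 36 without the macrophage library.

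Pearson's r, in the same order of pairs, was 0.928, 0.985, 0.959, 0.916, 0.896 and 0.971 with a minimum of 1 CPM. With a minimum of 50 CPM it was 0.783, 0.967, 0.848, 0.728, 0.633 and 0.900. With 5 added to the CPM it was 0.887, 0.981, 0.925, 0.863, 0.822 and 0.950. Without the 100 most abundant genes it was 0.845, 0.973, 0.908, 0.812, 0.768 and 0.940. Over the 1000 most variable genes it was 0.529, 0.936, 0.820, 0.448, 0.390 and 0.899. The cause of these shifts was not tested.

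With 5 added, list medians that left their interval were chemokine ligands in CD103int DC against cDC1 (1.38, as reported 2.20), matrix and wound genes in cDC1 against macrophage (-2.07, as reported -2.58) and proliferation genes in CD103int DC against macrophage (1.29, as reported 1.71), cDC1 against cDC2 (0.94, as reported 1.20) and cDC1 against macrophage (1.58, as reported 1.89). T cell markers became 0.37 in cDC1 and 0.26 in cDC2 against macrophage (from 0.82 and 0.78), and NK cell markers -0.63 (from -1.54) in CD103int DC against cDC1. With 0.25 added, T cell markers became -2.21 and -2.0 in CD103int DC against cDC1 and cDC2, and 1.08 in cDC2 against macrophage. NK cell markers became -2.67 and -2.75 in the same 2 comparisons of the CD103int DC and 1.62 in cDC1 against macrophage (from 1.16). Fibroblast markers became -1.95 in CD103int DC against cDC2 and chemokine ligands -3.22 in cDC1 against macrophage (from -2.52). The added constant acts most on members of low level.

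With columns rescaled to equal totals, cDC1 markers in cDC2 against macrophage became 0.29 (from 0.02). MHC class I genes became -0.25 in CD103int DC against cDC1, -0.20 in CD103int DC against macrophage and 0.10 in cDC2 against macrophage (the last from -0.17). Glycolysis genes became 0.73 in CD103int DC and 0.57 in cDC2 against macrophage (from 0.47 and 0.30), proliferation genes 1.96, 2.24 and 0.93 in CD103int DC, cDC1 and cDC2 against macrophage (from 1.71, 1.89 and 0.70), and housekeeping genes 0.30 in cDC1 and 0.28 in cDC2 against macrophage (from -0.07 and 0.01). Where the mean of members replaced the median, 2 lists that stood apart from random lists changed sign. Mature or migratory DC genes in CD103int DC against macrophage went to 0.15, and chemokine receptors in CD103int DC against cDC1 to -0.24, since the mean gives more weight to members far from 0.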

Other observations

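The tests in this part of read depth, of exchanged labels and of carried cells were chosen only after the results were seen. So was that of distinct molecules on genes of 10 CPM or more. For distinct molecules on genes under 10 CPM and for the interleukin-4 response, the prediction was written before the test was run. Both of these tests address patterns already seen in these libraries. The interleukin-4 list was not among the lists fixed before the data were examined. The plasmacytoid DC markers had their highest levels in the cDC1 library, where 6 of 6 measured members were at least 2-fold above cDC2 (median 2.90, percentile 100) and 5 above macrophages (median 3.19, percentile 100). Against cDC1, the CD103int DC had 6 of 6 at least 2-fold lower (median -3.09, percentile 0), with medians of -0.30 against cDC2 and -0.79 against macrophages. The surface lectin Siglech was at 15, 1.38, 0.366 and 0.733 CPM, Ccr9 at 56.5, 2.85, 1.96 and 5.34, the transcription factors Tcf4 at 501, 70.7, 63.2 and 110.2 and Runx2 at 76.9, 21.8, 14.5 and 39.4, Lag3 at 86.5, 10.02, 8.50 and 4.91 and Pacsin1 at 26.4, 2.24, 3.08 and 1.32. The immunoglobulin heavy chain gene Ighm (148, 30.4, 22.4 and 73.0 CPM), 1 of the 2 measured B cell markers beside Cd79b (2.77, 3.26, 1.43 and 3.68), and the endothelial growth factor receptor Kdr (425, 110.3, 63.9 and 239) were highest in cDC1 as well. Endothelial markers had medians of -1.24, -0.37 and -0.67 over 4 measured genes in the CD103int DC against cDC1, cDC2 and macrophages. Langerhans cell markers had medians of -0.76 and 1.33 against cDC1 and macrophages, with Cdh1 at 416, 118, 195 and 87.9 CPM.

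Measured T cell, NK cell, fibroblast, neutrophil, epithelial and red blood cell markers had median levels below 10 CPM in every library. Members above this included Klrk1 (140.7, 91.4, 83.9 and 85.1 CPM) and Csf3r. T cell markers in the CD103int DC had medians of -1.24 and 0.26 against cDC1 and macrophages, NK cell markers of -1.54 and -0.40, and fibroblast markers of 0.06 (-0.03 with columns rescaled to equal totals, mean -0.34) and -0.77. Neutrophil markers had medians of 0.74, -0.20 and -1.07 against cDC1, cDC2 and macrophages over 3, 3 and 4 genes, led by Csf3r (8.87, 62.2, 33.2 and 157 CPM). Of the epithelial markers 2 of 10 were measured, among them Krt8 (3.20, 1.29, 1.03 and 1.12 CPM), and of the red blood cell markers Hba-a2 (0.775, 0.562, 0.371 and 2.09). Of the mast cell and basophil markers 0 of 8 were in the table. Genes of retinoid metabolism, a list made after Aldh1a2 and Dhrs9 had been seen, had 6 of 12 members measured and medians of 0.87, 0.36 and 0.85 in the CD103int DC against cDC1, cDC2 and macrophages. Dhrs9 was at 10.3, 12.3, 27.8 and 7.2 CPM and Dhrs3 at 7.28, 32.7, 46.5 and 18.4, both outside the rule for named genes and chosen after their values were seen.

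The cDC1 library listed 454 genes at 0, of which 432 were under 10 CPM in every other library, against 19, 10 and 20 genes at 0 in the others. Lower depth was argued against, since the other libraries thinned to its depth would list at most 22.3 genes at 0. Fewer distinct molecules in the cDC1 library may account for these zeros. The upward spread around the mean of cDC2 and CD103int DC was taken at 1 to 3 CPM over that at 30 to 100 CPM. It was 2.77 in cDC1 and 1.5 in macrophages, a ratio of 1.84, above the bound set before the test was run. The cDC1 profile also lay farther from cDC2 and CD103int DC (r = 0.834 and 0.863) than the macrophage profile (r = 0.946 and 0.918). True differences at low levels could widen its spread too, so fewer molecules and lower levels in cDC1 cannot be told apart here. Of the 22 genes at 0 in cDC1 with 10 CPM or more elsewhere, Gm42742 overlaps Pagr1a, and their sum is level between cDC1 and CD103int DC (23.1 and 20.8 CPM). For the other 21, such as Retnla, Ctsk, Ccl7 and Gpr31b, 7.09 genes at 0 (3 to 17) were expected at the rate of stable genes of the same lowest level elsewhere, a test that replaced 2 earlier forms. The first could not decide, and the second, with the same outcome, took no account of that level. Fewer molecules alone were thus argued against for the 21 as a set, while fewer molecules together with a lower level in cDC1 stay open.

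The library labelled cDC2 held macrophage markers at the level of the macrophage library, with Csf1r at 1096 against 1538 CPM, and C1qa, chosen after its values were seen, at 572 against 105. MHC class II genes were higher in the library labelled cDC2 for 12 of 12 members (median 0.88). This could not decide on an exchange of these 2 labels, since cDC2 markers (median 0.04) and pan-cDC markers (median -0.23) did not separate the 2 libraries. Cells like those of the macrophage library carried in the cDC2 sort were argued against only as the sole source of these levels. With cDC1 as the base, the monocyte list implied a median of 10.2% of such cells (quartiles 6.79% to 26.5%). The macrophage list implied quartiles of 63.7% to 160%, and 160% is more than a mixture can give. The list medians already seen (-2.26 and -0.02) fixed the direction of this outcome. A smaller share of carried cells stays possible. Cells of another macrophage type in the cDC2 gate, or macrophage genes in the cDC2 themselves, stay open and were not tested.

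Itgae in the CD103int DC lay between cDC1 and cDC2, and carried cDC1 cells could give such a level. The share of cDC1 cells implied by Itgae was 15.9% (14.7 to 17.2). The 95th percentile of the 60 other genes at least 8-fold higher in cDC1 than in cDC2 was 14.5%. Of these genes 3 lay above Itgae. This could not decide on carried cells for Itgae, which lay at the edge of widely spread shares under a rule set after the results. The share also takes cDC2 as the base, and Itgae was higher in macrophages (5.50 CPM) than in cDC2 (1.1). The other genes implied a median of 3.09% (quartiles 0.389% to 6.94%), and for their low levels a few carried cDC1 cells and expression in the population itself cannot be told apart, since shares spread too widely to point to 1 source. A mixture of the other 3 populations cannot exceed the highest of them, yet 28 genes lay at least 2-fold above every other library. With no replicate to give the spread between libraries, the farthest such gene of cDC2 (Ccl8, 1.75 on the log2 scale) was taken as the yardstick. In the CD103int DC 8 genes lay beyond it, such as Aldh1a2, Fcrls and Retnla, with Palld only just. Their counting intervals above 1 followed from picking genes this far above, and cover counting error only. This could not decide on carried cells for these 8, since the spread between libraries is unknown and the yardstick rests on 1 gene. For the other 20 genes, carried cells and expression in the CD103int DC cannot be told apart either, since cDC2 had 11 genes by the same rule. A population of its own, cells of a kind not sorted here, and the treatment of the mice stay open.

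Because Retnla, Alox15, Mgl2 and Ear2, known as interleukin-4 targets in macrophages, were highest in the CD103int DC, a wider interleukin-4 response than in cDC2 was put to a test on 12 other genes of that response. The median difference was -0.00 with percentile 44.3, and 0 of 12 genes were 2-fold apart. For these 12 genes the hypothesis was thus not borne out against cDC2, and targets outside the list were not part of the test. Against cDC1 and macrophages the same list had medians of 1.60 (percentile 100) and 0.34 (percentile 98.8), both above the middle 95% of random lists.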
